A study of Mus musculus with 6 samples.

How the data were processed

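Messenger RNA of newborn mouse epidermis was measured in 6 libraries, 3 labelled control and 3 labelled as the Znf750 knockout, written Znf750_cKO below after the sample labels. Per the labels' protocols, back skin of postnatal day 0 pups was kept in dispase in the cold, the epidermis was lifted from the dermis and broken up with trypsin, and RNA was extracted from the cell suspension. The labels' protocols also name poly(A) selection, a kit that is not stated to mark strand, and 100-nucleotide single reads. No cell sort is named, so cells other than keratinocytes may have stayed in the suspension.

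The deposited values are FPKM per the file headers, fragments per kilobase of transcript scaled to the mapped fragments of the library, with 1 value for each of 55487 Ensembl genes in every library. Per the submitters' processing notes, the tools were Trim Galore 0.4.5, cutadapt 1.15, STAR 2.5.2a, RSEM 1.2.28, FastQC 0.11.8, MultiQC 1.0 and DESeq2, with the builds GRCm38 and mm10. These notes give the tools no role, and the annotation release and any filter are not given in the sources used here. The values are printed to the second decimal and the libraries' FPKM sums differ. RSEM divides reads that fit several genes between them by their estimated abundance, so levels of near-identical family members such as the Lce, Sprr2, keratin and globin genes are uncertain one by one. The strand of the reads is not stated, so reads of genes that overlap on opposite strands are not separated.

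The design fixed before the data were examined assumed a count table. The files hold FPKM, so the fallback written with that design was used: limma with an intensity trend and robust variances on log2(FPKM + 1), with group as the only term. Genes with an FPKM of at least 1 in at least 3 libraries were tested, which kept 13688. Fold changes are therefore on the log2(FPKM + 1) scale and understate the change of genes with low values. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. "Rose" and "fell" are used for genes past this threshold. Errors beside mean FPKM values are SDs over 3 libraries. The CPM minimum in the rule for named genes was read as FPKM. Analyses used R 4.3.3, limma 3.58.1 and statmod 1.5.0, and plots used Python 3.11.15 with matplotlib 3.10.9.

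Gene symbols came from a table that matched 55141 of the identifiers and left 346 without a symbol. Coordinates are those of the GENCODE mouse release M21 on GRCm38, which holds 99.5% of the identifiers.

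Before the data were examined, 29 gene lists were written from textbook knowledge of skin, covering epidermal differentiation, lipids, proteases, junctions, stress, cell cycle, other cell types and sample quality. The 25 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 25 lists. Camera with an estimated correlation and fry were run beside it. Each list also has counts of members that rose or fell over all genes, and counts adjusted over the list alone. The genes named were chosen by a rule set at the same time. It takes Zfp750, the 8 genes with the highest and the 8 with the lowest log2 change among changed genes with a known symbol, a mean FPKM of at least 2 and groups that do not overlap. It adds, from each epidermal list, the 2 members with the smallest p in each direction among changed genes, or the most abundant member if none changed. From each list of other cells or of quality it takes the most abundant member and the member with the smallest p if that one changed. Other genes named were chosen after their values were seen.

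Read depth is not given with FPKM values, but it leaves steps in them. For genes with 1 annotated transcript, FPKM times the transcript length less 99 bases should be a whole multiple of a step set by depth. Values fell within 0.1 read of a whole number for 63.0% to 74.7% of such values per library, where chance gives 20%. The steps place the depth between 21.4 and 35.4 M reads (megareads) per library, and a single read on a transcript of 1 kilobase at an FPKM of 0.0283 to 0.0468. The step search and its settings were settled after the values were seen, so these depths are estimates, and they entered no test.

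The labels number the replicates 1 to 3 in both groups. After each gene's group mean was taken off, libraries with the same number correlated across genes at 0.31, 0.17 and 0.48 for numbers 1, 2 and 3. Of libraries with unlike numbers, control replicate 1 and Znf750_cKO replicate 2 correlated at 0.24, and the other 5 such correlations were negative. The 3 values for like numbers exceed 0.1, the limit set for treating the numbers as pairs, so a fit with the replicate number as a block was run beside the unblocked one. The pairing is an assumption taken from the data, since the labels do not say what a number stands for. Taking off group means makes the 3 deviations of a group sum to 0. Likeness of the third replicates alone therefore raises the correlations among numbers 1 and 2 as a set. Pairing of numbers 1 and 2 is not shown, since 0.24 for unlike numbers exceeds 0.17 for number 2. The labels also do not say that libraries come from separate animals, so p-values measure the spread between these libraries.

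On simulated data with the real genes' means and spread, 67 of 100 genes with a log2 change of 1 and 84 of 100 with a change of 2 were called, together with 9 of 13488 genes without a change. A simulated set without any change gave 0 calls among the 13688 genes, and a list shifted by 1 was recovered together with 1 other list. Noise was drawn independently for each gene and library. In the real data the shifted list, that of the basal layer, had an estimated correlation of 0.50 between genes. The runs therefore do not measure false calls that correlated genes or replicate numbers would cause. Single-gene changes were put on genes with a mean FPKM of at least 2, and the less abundant of these were only raised.

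Alternatives tried were other scalings of the libraries, other pseudocounts, no filter on low values, stricter thresholds, other variance settings, the replicate block, each replicate left out in turn, other list tests, and replicate 3 of both groups left out. The alternatives without a variance trend, without mitochondrial genes in the scaling and without replicate 3 of both groups were added after the data were seen. All 6 libraries were used, and the files held no other samples.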

Results

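Epidermal RNA was compared between 3 control and 3 Znf750_cKO libraries from newborn mice at postnatal day 0. Znf750, whose mouse gene symbol is Zfp750, encodes a zinc finger transcription factor of differentiating keratinocytes, and the series asks what its loss does to the developing epidermis. The libraries held an estimated 28.4, 21.4 and 23.3 M reads (megareads) in control replicates 1, 2 and 3, and 35.4, 26.6 and 23.0 M reads in Znf750_cKO replicates 1, 2 and 3. The number of genes listed above 0 ranged from 24045 to 29087 per library.

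The targeted gene was measured first. Zfp750 (ENSMUSG00000039238, chromosome 11, 121510978 to 121519333, minus strand, GRCm38) lies within the span of Tbcd, which runs on the plus strand, and shares no annotated exon sequence with it. Its level was 44.8, 32.0 and 34.9 FPKM in the control libraries and 0.99, 0.83 and 1.47 FPKM in the Znf750_cKO libraries. It fell from 37.3 ± 6.71 to 1.10 ± 0.33 FPKM (mean ± SD, n = 3 per group), a 34.0-fold difference of means, with a log2 change of -4.19 (SE 0.17, limma adjusted p = 4.6e-05). Tbcd stood at 15.5 ± 2.61 FPKM in control and 19.6 ± 4.75 in Znf750_cKO (log2 change 0.31, adjusted p = 0.41). The Zfp750 levels of the groups did not overlap.

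Among genes that rose, a pair of type II keratins stood far apart from the rest. Krt2, a keratin of upper epidermal layers, rose from 0.26 ± 0.06 to 256 ± 81.3 FPKM (log2 change 7.62, SE 0.23, limma adjusted p = 1.4e-05). Krt8, a keratin of simple epithelia, rose from 3.45 ± 0.28 to 241 ± 40.4 FPKM, 69.8-fold (log2 change 5.75, SE 0.14, adjusted p = 1.8e-06). They lie in the keratin cluster of chromosome 15, Krt2 (ENSMUSG00000064201) at 101810689 to 101818169 and Krt8 (ENSMUSG00000049382) at 101996698 to 102004482, both on the minus strand. The other 6 genes with the highest changes were Fabp4, a fatty acid binding protein (0.36 to 7.63 FPKM), Slc15a3, a lysosomal transporter (2.11 to 16.7), the cornified envelope precursor Sprr1b (25.8 to 151), the urea cycle enzyme Arg1 (3.58 to 23.1), trichohyalin, Tchh (14.2 to 80.2), and the tight junction protein Cldn7 (1.10 to 8.31). Their log2 changes ran from 2.67 for Fabp4 to 2.16 for Cldn7. With 1 library left out, Tchh passed in 1 and Arg1 in 5 of 6 fits, and the other 6 genes of these 8 passed in each. Krt8 overlaps the antisense gene Gm36026 and Slc15a3 overlaps Tmem132a, and the unstated strand leaves their reads unseparated.

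**Figure D1:**
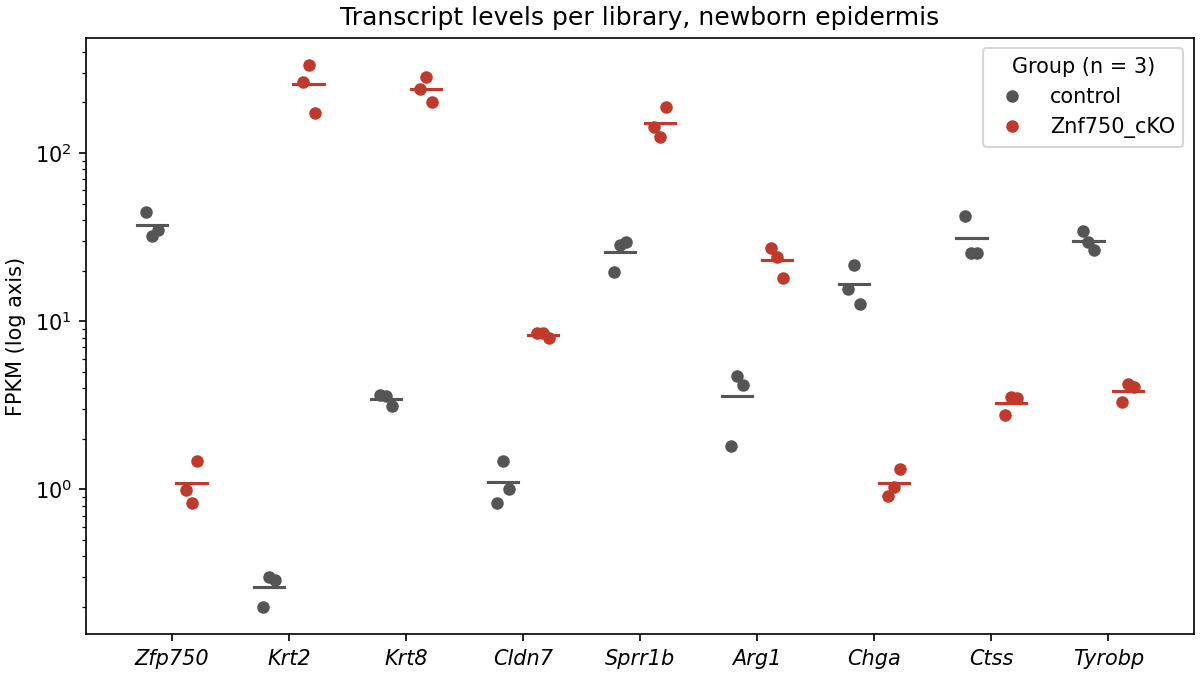
FPKM on a log axis for 9 genes in each library, with control in grey and Znf750_cKO in red, points for the 3 libraries of a group and bars for their mean. For each gene shown the groups do not overlap, as for Krt2 with 0.20 to 0.30 FPKM in control and 172 to 334 FPKM in Znf750_cKO.

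Next to Zfp750, the genes that fell most were Snord13, Chga, Sprr4, Ctss, Wfdc21, Cd74 and Tyrobp. Chga, which encodes the secretory granule protein chromogranin A, fell from 16.6 ± 4.55 to 1.09 ± 0.21 FPKM (log2 change -3.05, SE 0.20, limma adjusted p = 0.00045). The lysosomal protease Ctss fell from 31.1 ± 9.69 to 3.27 ± 0.44 FPKM (log2 change -2.88), the invariant chain Cd74 from 24.1 ± 9.78 to 2.42 ± 0.57 (log2 change -2.82), and the signalling adaptor Tyrobp from 30.1 ± 4.05 to 3.86 ± 0.49 (log2 change -2.67). Wfdc21, a WAP domain protein, fell from 197 ± 96.3 to 25.5 ± 5.43 FPKM (log2 change -2.82, adjusted p = 0.018), and passed in 4 of 6 fits that leave out 1 library. Sprr4 was listed at 0 in all 3 Znf750_cKO libraries, against 12.2, 7.33 and 3.19 FPKM in control (adjusted p = 0.012), and passed in 3 of the 6. Snord13 was also listed at 0 in Znf750_cKO, against 11.1, 21.4 and 17.8 FPKM in control (adjusted p = 0.00021), but it is a short RNA that poly(A) selection and 100-nucleotide reads measure poorly.

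Across all tested genes, 577 of 13688 (4.22%) changed in limma at an adjusted p under 0.05, of which 152 rose and 425 fell, and 2914 had an unadjusted p under 0.05. In the fit with the replicate number as a block, 136 rose and 256 fell, and 332 of the 577 genes were called there too. Lower genes exceeded higher ones under each of 5 other scalings, least after rescaling by median ratios, which centres the median log2 change near 0, where 258 rose and 295 fell. In the other 4 scalings 124 to 163 rose and 320 to 366 fell. The count was 196, 167 and 292 without control replicate 1, 2 or 3, 100, 355 and 356 without Znf750_cKO replicate 1, 2 or 3, and 390 without replicate 3 of both groups. Of 40 named genes that changed, 17 passed in each of the 6 fits that leave out 1 library, among them Zfp750, Krt2, Krt8, Fabp4, Slc15a3, Sprr1b, Cldn7, Chga, Ctss, Cd74, Tyrobp and Snord13. The number of the 40 that passed was between 18 and 34 per fit, lowest without Znf750_cKO replicate 1. The groups did not overlap in any of the 577 changed genes, nor in 28.01% of tested genes, where chance gives 10%. Of the 577 changed genes, 7 were listed at 0 in all libraries of a group. Of 25 gene lists tested, 11 passed camera, and 0 did with an estimated correlation, where 3 had an unadjusted p under 0.05. Splits of the libraries that mix the groups passed camera at the preset correlation in 2 to 10 lists. A camera call at that setting therefore does not by itself show a difference between the groups.

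Cornified envelope genes moved in both directions. Of 25 tested genes of cornification, 2 rose, 4 fell and 19 did not pass (2 and 7 adjusted over the list alone). Tchh rose as above, and involucrin, Ivl, an early envelope precursor, rose from 44.5 ± 16.8 to 152 ± 27.0 FPKM (log2 change 1.79, limma adjusted p = 0.022, and 0.058 with the block). Casp14, a protease of filaggrin breakdown, fell from 127 ± 34.9 to 50.5 ± 9.60 FPKM (log2 change -1.29, adjusted p = 0.025), and Padi1, which deiminates keratins and filaggrin, fell from 1.72 ± 0.35 to 0.10 ± 0.05 FPKM (log2 change -1.31, adjusted p = 0.012). Scel and Krt80 fell as well, at adjusted p = 0.042 and 0.035. Scel passed under 0 and Krt80 under 2 of 5 other scalings (limma adjusted p from 0.054 to 0.073 and from 0.049 to 0.065), and Krt80 had an adjusted p of 0.069 with the block. The major envelope proteins did not pass: loricrin, Lor, stood at 3058 ± 940 FPKM in control and 2485 ± 307 in Znf750_cKO, and filaggrin, Flg, at 1656 ± 565 and 903 ± 135 (adjusted p = 0.10). As a whole the list had an camera adjusted p of 0.97. Ivl passed in 2 of 6 fits that leave out 1 library, and under other scalings 2 or 3 members fell. Members past limma numbered 1, 2 and 4 without control replicate 1, 2 or 3, and 0, 1 and 5 without Znf750_cKO replicate 1, 2 or 3.

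Late cornified envelope genes encode small proteins of the outermost envelope. Of 19 tested members 17 had a negative log2 change, with a median of -0.87. None passed limma one by one over all genes, while 11 had an unadjusted p under 0.05 and 3 fell adjusted over the list alone. The most abundant member, Lce1m, stood at 1701 ± 716 FPKM in control and 828 ± 182 in Znf750_cKO (log2 change -0.98, adjusted p = 0.14). The list passed camera downwards at an adjusted p of 0.00052, with adjusted p = 0.59 with an estimated correlation. Over all genes 5 members fell without Znf750_cKO replicate 3, and 9 fell without replicate 3 of both groups, with a median of -1.32.

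Small proline-rich genes went both ways. Of 11 tested members, 2 rose, 1 fell and 8 did not pass (2 and 2 adjusted over the list alone), with a median log2 change of 0.40. Sprr1b rose 5.86-fold and Sprr2d rose from 16.1 ± 2.35 to 53.9 ± 20.7 FPKM (log2 change 1.63, limma adjusted p = 0.024), while Sprr4 fell as above. Sprr2d passed in 2 of 6 fits that leave out 1 library. Camera placed the list upwards at an adjusted p of 0.011, with adjusted p = 0.59 with an estimated correlation. That camera call ended without replicate 3 of both groups (0.46, with a median of -0.00044), without control replicate 3 (0.092), without Znf750_cKO replicate 3 (0.098) and with median-ratio scaling (0.067).

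The list of suprabasal keratins and of desmosomes also holds Ptgs1, Notch3 and Hes1. Of its 18 tested members, 2 rose, 1 fell and 15 did not pass (2 and 1 adjusted over the list alone). Krt2 rose, the desmosomal cadherin Dsg3 rose from 34.5 ± 6.97 to 70.8 ± 11.6 FPKM (log2 change 1.02, limma adjusted p = 0.024), and Krt78 fell from 35.6 ± 9.27 to 16.8 ± 2.48 (log2 change -1.02, adjusted p = 0.030, and 0.0502 with the block). Krt1 and Krt10, the main suprabasal keratins, stood at 7927 ± 1585 and 9563 ± 2000 FPKM in control and at 8961 ± 1934 and 11485 ± 2981 in Znf750_cKO, with adjusted p = 0.69 and 0.58. The list passed camera upwards at an adjusted p of 0.0060, with adjusted p = 0.58 with an estimated correlation. Its members had a median log2 change of 0.11 and a mean of 0.49, with Krt2 at 7.62. The list was not tested without Krt2, so the call does not show a rise of the list as a whole. Only 1 member rose without control replicate 2 or 3 or Znf750_cKO replicate 1 or 3, and Krt78 passed in 1 of the 6 fits that leave out 1 library, the one without control replicate 3.

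Of 17 tested genes of the basal layer, 4 rose, 3 of them integrin chains, and 13 did not pass. In this list 9 rose adjusted over the list alone, and 15 had a positive log2 change, with a median of 0.45. Itga3 rose from 38.1 ± 8.28 to 81.8 ± 15.6 FPKM (log2 change 1.09, limma adjusted p = 0.030) and Itgb1 from 74.4 ± 9.16 to 131 ± 17.5 (log2 change 0.81, adjusted p = 0.021), which encode the chains of a laminin receptor. Itgb4 and the cadherin Cdh3 also rose, with log2 changes of 0.67 and 0.61, and each passed under 2 of 5 other scalings. Itga3 passed under 4 of the 5, and 1 to 5 members of the list rose under them. In the blocked fit 7 members rose. Krt5 stood at 6632 ± 349 FPKM in control and 6740 ± 147 in Znf750_cKO, and Krt14 at 5268 ± 303 and 6799 ± 677, neither past the threshold. In camera the list was higher at an adjusted p of 7.1e-07, with adjusted p = 0.58 with an estimated correlation. With any 1 library left out 0 to 2 members rose, and 0 did without control replicate 2, control replicate 3, Znf750_cKO replicate 1 or replicate 3 of both groups.

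Among junction genes, a pair of claudins rose. Cldn7 rose 7.53-fold, and Cldn4 rose from 38.8 ± 8.36 to 73.8 ± 6.41 FPKM (log2 change 0.93, limma adjusted p = 0.023, and 0.062 with the block). The other 15 of 17 tested members did not pass (3 rose and 2 fell adjusted over the list alone), and camera gave an adjusted p of 0.096. That p was 0.028 without replicate 3 of both groups and 0.024 without Znf750_cKO replicate 3, and only Cldn7 rose without control replicate 1 or 2 or Znf750_cKO replicate 1 or 2.

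Genes of desquamation, the shedding of the outer layers, were lower in part. Of 17 tested proteases and inhibitors of desquamation, 4 fell and 13 did not pass (3 rose and 9 fell adjusted over the list alone). The kallikreins Klk10 and Klk11 fell from 32.4 ± 5.44 to 15.2 ± 1.33 FPKM and from 54.2 ± 3.56 to 31.0 ± 3.92 (log2 changes -1.03 and -0.79, limma adjusted p = 0.012 and 0.016). None of the other tested kallikreins passed. Klk5, Klk6 and Klk7 had log2 changes of 0.24, 1.14 and 0.20, and Klk8, Klk13 and Klk14 of -0.68, -0.76 and -0.11. Prss8, a membrane protease, fell from 27.4 ± 4.91 to 13.7 ± 1.71 FPKM (adjusted p = 0.018, and 0.055 with the block), and the inhibitor Serpinb12 from 180 ± 50.1 to 95.6 ± 7.38 (adjusted p = 0.049). Serpinb12 passed under 3 of 5 other scalings, and with median-ratio scaling 2 members rose and 3 fell over all genes. Camera gave an adjusted p of 0.18, and 0.032 without control replicate 1. The count that fell was 4 without control replicate 1, 1 without control replicate 2, 0 without Znf750_cKO replicate 1 and 3 without each of the others.

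Few lipid genes passed limma one by one. Of 27 tested genes of barrier ceramides and lamellar bodies, 1 fell and 26 did not pass (1 fell adjusted over the list alone): Aloxe3, a lipoxygenase of barrier ceramides, went from 37.9 ± 6.49 to 19.5 ± 4.42 FPKM (log2 change -0.93, limma adjusted p = 0.043, and 0.082 with the block). Of 22 genes of cholesterol synthesis, Hmgcs1 rose from 78.9 ± 5.55 to 109 ± 5.56 FPKM (adjusted p = 0.045, and 0.069 with the block), Hsd17b7 fell from 15.0 ± 1.14 to 9.47 ± 1.43 (adjusted p = 0.045) and 20 did not pass (1 and 2 adjusted over the list alone). Of 17 genes of fatty acid and triglyceride synthesis, 2 fell and 15 did not pass (4 fell adjusted over the list alone). These were the elongase Elovl7, from 45.4 ± 5.54 to 25.6 ± 3.75 FPKM (adjusted p = 0.023, and 0.062 with the block), and the lipid droplet protein Plin2, from 17.2 ± 2.41 to 8.06 ± 2.24 (adjusted p = 0.034, and 0.0502 with the block). The camera adjusted p was 0.63 for ceramides and 0.18 for each of the other lipid lists. The list of fatty acid and triglyceride synthesis passed fry downwards at an adjusted p of 0.0057, and 0.048 with the block, with 12 of 17 members negative. With 1 library left out, Hmgcs1 passed in 0 of 6 fits, Aloxe3 and Hsd17b7 in 1, and Elovl7 and Plin2 in 2, and under 5 other scalings Aloxe3 and Hsd17b7 passed in 1 and Hmgcs1 in 3. For cholesterol synthesis camera gave an adjusted p of 0.0055 without control replicate 2 and 0.017 without Znf750_cKO replicate 1.

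Transcripts of 3 secreted stress proteins rose. Of 19 tested stress keratins, alarmins and cytokines, 3 rose and 16 did not pass (8 rose and 1 fell adjusted over the list alone). Slpi, a secreted protease inhibitor, rose from 0.41 ± 0.21 to 4.79 ± 1.14 FPKM (log2 change 2.03, limma adjusted p = 0.0041), S100a9 from 2.38 ± 0.81 to 8.41 ± 2.09 (log2 change 1.48, adjusted p = 0.019), and the cytokine Il1f6 from 10.0 ± 5.85 to 38.8 ± 5.09 (log2 change 1.97, adjusted p = 0.043, and 0.071 with the block). S100a8, of the same list, stood at 0.94 ± 0.85 FPKM in control and 2.24 ± 2.15 in Znf750_cKO, with overlapping groups (limma adjusted p = 0.54). Krt6b went from 9.85 ± 4.07 to 72.7 ± 43.1 FPKM with an adjusted p of 0.058, while Krt16 stood at 226 ± 43.3 in control and 194 ± 76.2 in Znf750_cKO. The list passed camera upwards at an adjusted p of 0.00037, with adjusted p = 0.59 with an estimated correlation and 0.070 without replicate 3 of both groups, where the median turned from 0.33 to -0.12. With 1 library left out, Slpi passed in 6, S100a9 in 4 and Il1f6 in 1 of 6 fits.

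Of 10 tested S100 genes, S100a4 fell from 17.3 ± 2.55 to 4.67 ± 1.67 FPKM (log2 change -1.72, limma adjusted p = 0.0070) and 9 did not pass (2 rose and 3 fell adjusted over the list alone). The median log2 change of this list was -0.07 while camera pointed up, at an adjusted p of 0.97, and the median turned positive under median-ratio scaling, 1 of 5 other scalings, where 1 member rose. Among 23 transcription factors of epidermal differentiation, 2 rose and 21 did not pass (5 rose adjusted over the list alone). Grhl3, a grainyhead factor, rose from 19.5 ± 0.81 to 36.3 ± 3.95 FPKM (log2 change 0.86, adjusted p = 0.0087), and Maf rose from 7.87 ± 1.13 to 15.8 ± 1.17 (log2 change 0.93, adjusted p = 0.013). This list passed camera upwards at an adjusted p of 0.00030, with adjusted p = 0.39 with an estimated correlation, and 3 to 5 members rose under the other scalings and 1 without Znf750_cKO replicate 1.

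None of 29 tested cell cycle genes passed limma over all genes or adjusted over the list alone, 10 had a negative change at an unadjusted p under 0.05, and the median log2 change was -0.21. Pcna, the most abundant member, stood at 114 ± 7.69 FPKM in control and 108 ± 6.36 in Znf750_cKO (adjusted p = 0.75). Camera placed the list downwards at an adjusted p of 0.018, with adjusted p = 0.59 with an estimated correlation, and lost the call without control replicate 1 (0.12), without Znf750_cKO replicate 3 (0.13) and with median-ratio scaling (0.066). Among 10 interferon-stimulated genes and 16 NRF2 targets none passed limma, with 3 and 4 at an unadjusted p under 0.05 and camera adjusted p = 0.17 (0.048 without replicate 3 of both groups) and 0.75. Adjusted over the list alone, 1 interferon-stimulated gene fell and 0 NRF2 targets changed. Irf7 stood at 18.5 ± 8.01 FPKM in control and 7.54 ± 2.79 in Znf750_cKO (adjusted p = 0.12), and Tkt at 73.3 ± 3.15 and 73.5 ± 4.91.

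Markers of immune cells were lower throughout. All 9 tested members of 12 fell, over all genes and adjusted over the list alone, with a median log2 change of -2.33. Beside Tyrobp and Cd74 these were Cd52 (21.8 to 3.01 FPKM), Fcer1g (18.2 to 3.27, adjusted p = 0.090 with the block), Laptm5 (15.6 to 2.37), Csf1r (12.2 to 1.59), Lyz2 (6.22 to 0.41), Ptprc (5.57 to 1.06) and Adgre1 (4.32 to 0.54). The list passed camera downwards at an adjusted p of 1.4e-11, with adjusted p = 0.39 with an estimated correlation. Of T cell genes, Cd3g stood at 2.71 ± 0.36 FPKM in control and 1.33 ± 0.84 in Znf750_cKO (log2 change -0.73, limma adjusted p = 0.16), with no overlap of the groups, and Cd3e and Cd3d were below the filter, at 0.83 ± 0.41 and 0.61 ± 0.20 FPKM in control and 0.67 ± 0.61 and 0.45 ± 0.22 in Znf750_cKO. With any 1 library left out, 6 to 8 of the 9 members fell. Under 5 other scalings 8 to 9 fell, and Fcer1g passed under 3 of these.

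Melanocyte and dermal fibroblast markers did not pass, while an erythroid marker fell and a pair of Merkel cell markers rose. The 8 melanocyte markers had a median log2 change of 0.08 with 0 past limma and 0 at an unadjusted p under 0.05, and Dct stood at 54.2 ± 17.8 FPKM in control and 55.8 ± 1.30 in Znf750_cKO (camera adjusted p = 0.32, and 0.00084 without control replicate 1). Of 8 dermal fibroblast markers none passed limma, 1 had an unadjusted p under 0.05 and 1 fell adjusted over the list alone (camera adjusted p = 0.72). Postn stood at 215 ± 19.99 FPKM in control and 187 ± 17.5 in Znf750_cKO. Of 3 erythroid markers, the globin Hba-a2 fell from 15.3 ± 4.56 to 3.59 ± 0.46 FPKM (log2 change -1.80, limma adjusted p = 0.0055), 2 did not pass, and 2 fell adjusted over the list alone (camera adjusted p = 0.017, with adjusted p = 0.58 with an estimated correlation). Of 3 tested Merkel cell markers, Krt8 and Krt18 rose (2 adjusted over the list alone), Krt18 from 1.07 ± 0.35 to 3.71 ± 0.83 FPKM, and Krt20 stood at 1.24 ± 0.21 and 0.76 ± 0.18 (adjusted p = 0.32). That list passed camera upwards at an adjusted p of 0.0034, with adjusted p = 0.39 with an estimated correlation. It was not tested without Krt8, at a log2 change of 5.75, so the call does not show a rise of the list as a whole. Hba-a2 passed in each fit that leaves out 1 library, 2 erythroid markers fell without control replicate 3, and Krt18 passed in 1 fit, the one without Znf750_cKO replicate 3.

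Hair follicle markers went both ways. Of 14 tested, the transcription factor Lhx2 rose from 24.8 ± 2.36 to 43.3 ± 2.08 FPKM (log2 change 0.78, limma adjusted p = 0.011), the inner root sheath keratins Krt27 and Krt71 fell from 6.83 ± 2.55 to 0.58 ± 0.11 and from 6.66 ± 2.92 to 0.53 ± 0.13 FPKM (log2 change -2.25 each), and 11 did not pass (1 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.85). Without Znf750_cKO replicate 1 none rose and 1 fell, and 4 fell without control replicate 3. Of 4 sebaceous gland markers none passed limma, 2 had an unadjusted p under 0.05 and 2, Awat1 and Far2, fell adjusted over the list alone, with log2 changes of -1.41 and -0.90 (camera adjusted p = 0.24, and 0.028 without replicate 3 of both groups), and Mgst1 stood at 22.0 ± 7.38 FPKM in control and 29.4 ± 9.18 in Znf750_cKO. Markers of endothelium, skeletal muscle, Schwann cells and adipocytes had fewer than 3 tested members each and were not tested as lists. Their most abundant members were Pecam1 (16.1 and 16.5 FPKM in control and Znf750_cKO), Tnni2 (7.69 and 8.24), Mbp (6.57 and 6.72) and Fabp4, the only one of these that changed.

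**Figure D2:**
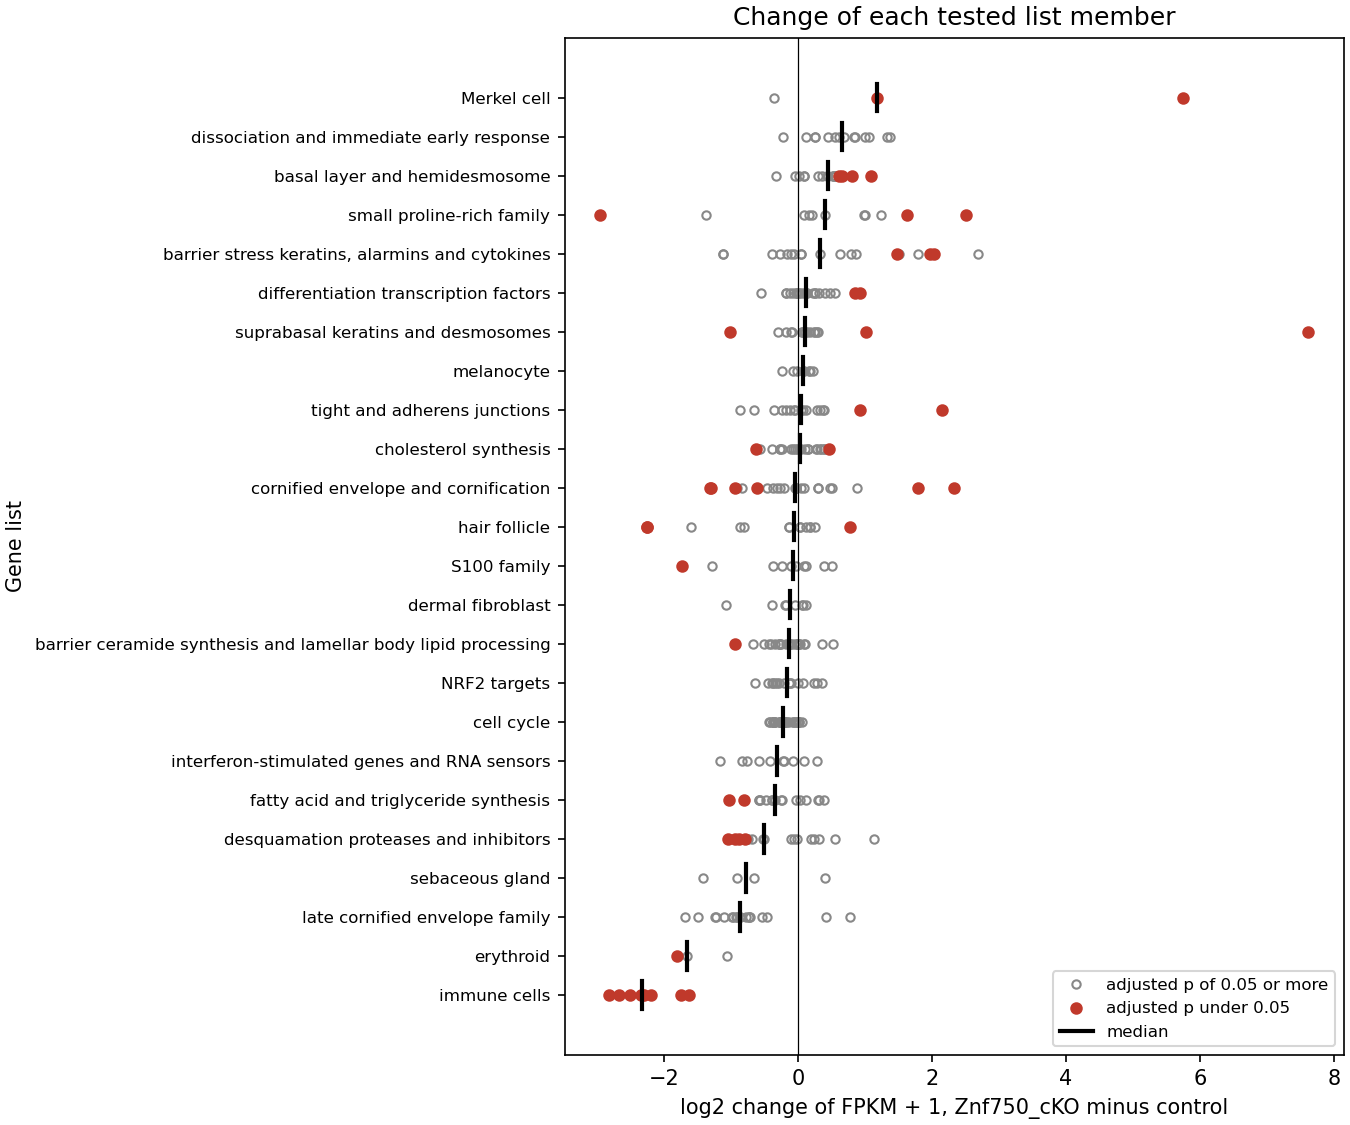
Log2 change of FPKM + 1 (horizontal axis, Znf750_cKO minus control) of every tested member of the tested gene lists other than the sex list (vertical axis, ordered by median), with filled red points for an adjusted p under 0.05, open points for the rest and a bar for the list median. Immune cell markers lie lowest, with a median of -2.33, and Krt2 and Krt8 lie farthest to the right at 7.62 and 5.75.

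The 14 immediate early genes, which respond to tissue handling, had a median log2 change of 0.65 and passed camera upwards at an adjusted p of 5.2e-05, with adjusted p = 0.59 with an estimated correlation. None passed limma one by one over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05, while 1 rose without Znf750_cKO replicate 2, without replicate 3 of both groups and with the block. Fos stood at 78.1, 92.0 and 247 FPKM in control replicates 1, 2 and 3 and at 269, 189 and 558 in Znf750_cKO replicates 1, 2 and 3 (limma adjusted p = 0.32, and 0.035 with the block). The mean log2 level of the 14 genes was 5.21 ± 0.28 in control and 5.87 ± 0.65 in Znf750_cKO (n = 3 per group, exact two-sided permutation p = 0.20, where the smallest possible is 0.10, adjusted over 5 measures 0.50). It was higher in Znf750_cKO in each of the 3 pairs of libraries with the same number, at 4.94 and 5.67, 5.19 and 5.34, and 5.51 and 6.59 in control and Znf750_cKO, and 3 pairs cannot give an exact p under 0.25.

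The third replicates of both groups stood apart from the other libraries. The first principal component of the 500 most variable genes held 46.7% of the variance and placed replicate 3 of both groups at one end, at 23.3 and 27.6. The second held 26.1% and separated the groups, from 8.84 to 17.6 in control and from -17.8 to -12.4 in Znf750_cKO. The third replicates had Xist at 104 and 82.1 FPKM against at most 0.11 in the others, and had a Ddx3y level of 0.04 FPKM each against 25.3 to 33.7 in the others, so each group held 1 library of a female pattern. Of the 4 tested sex genes 0 passed limma and 0 had an unadjusted p under 0.05 (median log2 change -0.04, positive under median-ratio scaling alone of 5 others, camera upwards at an adjusted p of 0.75, and 0 adjusted over the list alone), and Eif2s3y stood at 54.7, 45.2 and 0.09 FPKM in control and 45.9, 48.0 and 0.19 in Znf750_cKO. Spearman correlations between libraries averaged 0.960 within groups and 0.947 between them, with overlapping ranges of 0.936 to 0.978 and 0.924 to 0.961.

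**Figure D3:**
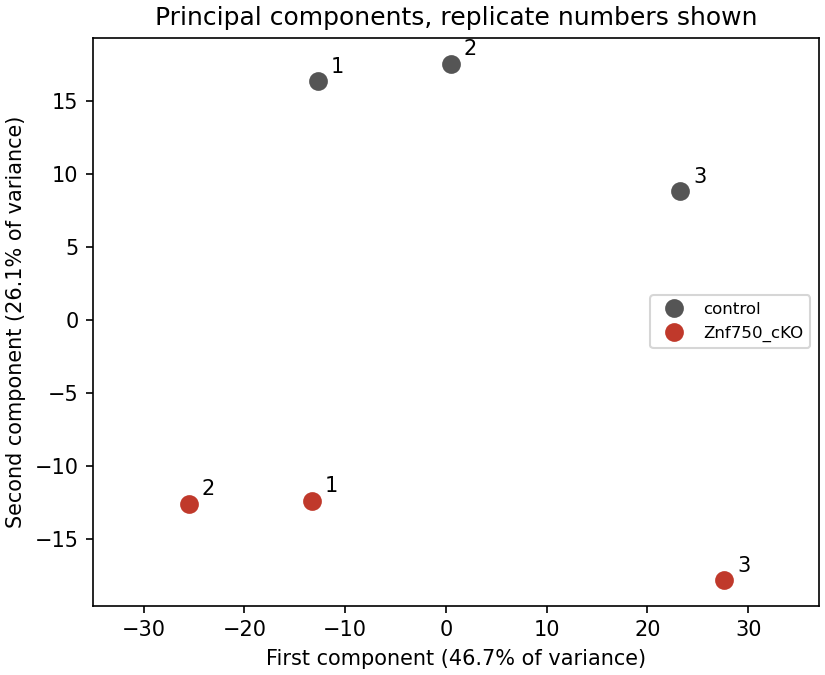
First and second principal components of log2(FPKM + 1) over the 500 most variable tested genes, with control libraries in grey, Znf750_cKO libraries in red and replicate numbers beside the points. The second component separates the groups and the first places replicate 3 of both groups at 23.3 and 27.6.

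Library make-up was compared on 5 measures, for which 3 libraries against 3 cannot give an exact p under 0.10. The 10 most abundant genes took 15.1 ± 0.82% of the FPKM sum in control and 15.1 ± 0.73% in Znf750_cKO (n = 3 per group, exact two-sided permutation p = 1, adjusted 1). Mitochondrially encoded genes took 15.5, 12.9 and 12.8% in control replicates 1, 2 and 3 and 12.5, 12.3 and 12.5% in Znf750_cKO replicates 1, 2 and 3, so the groups did not overlap on this count. The means were 13.7 ± 1.52% and 12.5 ± 0.16% (n = 3, exact two-sided permutation p = 0.10, the smallest possible, adjusted 0.50). This count leaves out the pseudogene Gm28661, which the scaling without mitochondrial genes treats as mitochondrial. Gm28661 stood at 8217, 8712 and 640 FPKM in control replicates 1, 2 and 3 and at 4770, 8680 and 6111 in Znf750_cKO replicates 1, 2 and 3. It was lowest in control replicate 3, and once it is counted that library falls below the Znf750_cKO libraries. The groups therefore overlap with this gene included, and the share with it was not tested. The number of genes with an FPKM of at least 1 was 13955 ± 273 in control and 13417 ± 815 in Znf750_cKO (n = 3, exact two-sided permutation p = 0.40, adjusted 0.67). Adjustment covered these 3 measures, the immediate early level and the number of genes listed above 0 (26798 ± 980.3 and 26796 ± 2552, exact two-sided permutation p = 1).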

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

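The alternatives without a variance trend, without mitochondrial genes in the scaling sums and without replicate 3 of both groups were chosen after seeing the data, and where a value changed, the cause was not tested unless stated. Zfp750, Krt2 and Krt8 kept their direction and stayed past the limma threshold in each alternative run. Counting each gene named by the rule, other than Zfp750, under each alternative except the stricter thresholds and the list tests, 786 results kept their side of the threshold, 129 were no longer past it, 3 newly passed, and 0 of the called genes turned direction. The replicate block ended the calls of Ivl, Aloxe3, Hmgcs1, Elovl7, Plin2, Krt78 and Cldn4, added Fos, and changed no other call of a gene named by the rule. Among the other genes named it ended the calls of Krt80, Prss8, Il1f6, Fcer1g, H2-Eb1, H2-Ab1 and Mrc1. Median-ratio scaling moved the median log2 change of all tested genes from -0.08 to 0.00042. Pseudocounts of 0.1 and 0.5 gave 528 and 576 changed genes, and non-robust variances and no variance trend gave 438 and 548.

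Changed genes, 577 with 152 higher and 425 lower, numbered 85 with 31 higher and 54 lower without a filter on low values, where 35621 genes were tested and 6 list members rose and 9 fell. They numbered 93 with 30 higher and 63 lower at an adjusted p under 0.01, and 289 with 68 higher and 221 lower with an absolute log2 change of at least 1, both by construction of a stricter rule. Median-ratio scaling gave 258 higher genes, the replicate block gave 256 lower genes, and without replicate 3 of both groups 95 genes were higher and 43 list members fell. Adjusted over the list alone, 41 list members rose and 54 fell. With 1 library left out the counts ranged from 100 to 356 changed genes, 34 to 110 higher, 66 to 259 lower, 8 to 18 list members that rose and 9 to 28 that fell, with fewer libraries by construction.

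Camera calls of lists were lost with an estimated correlation at an adjusted p of 0.586 for the late envelope, small proline-rich, barrier stress, cell cycle and immediate early lists, 0.580 for the suprabasal, basal and erythroid lists, and 0.388 for the transcription factor, immune and Merkel lists. With fry, which tests whether genes of a list move one way, adjusted p was 0.237 for late envelope, 0.319 for small proline-rich, 0.142 for basal, 0.295 for barrier stress and for immediate early, 0.0630 for cell cycle and 0.0624 for erythroid genes, while fatty acid synthesis passed at 0.00571. With fry and the block it was 0.390 for late envelope and for barrier stress, 0.576 for small proline-rich, 0.146 for suprabasal, 0.0623 for basal, 0.101 for transcription factor, 0.0673 for cell cycle, 0.218 for immediate early, 0.0670 for immune and 0.187 for erythroid genes, and fatty acid synthesis passed at 0.0478. Without a filter camera gave 0.106 for Merkel and 0.0634 for erythroid genes, and passed fatty acid synthesis and desquamation at 0.0208, interferon-stimulated genes at 4.72e-05 and sebaceous markers at 0.00321. With median-ratio scaling it gave 0.0669 for small proline-rich and 0.0659 for cell cycle genes. Without replicate 3 of both groups it gave 0.460 for small proline-rich and 0.0698 for barrier stress genes, and passed tight junctions and sebaceous markers at 0.0282 and interferon-stimulated genes at 0.0481. With 1 library left out camera ranged from 0.000824 to 0.0982 for small proline-rich, 0.00454 to 0.127 for cell cycle, 0.0318 to 0.473 for desquamation, 0.0055 to 0.752 for cholesterol, 0.0242 to 0.276 for tight junction and 0.00084 to 0.885 for melanocyte genes.

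Alternatives set before the data were seen with edgeR, DESeq2, voom, TMM, the filter on counts and unrounded counts need counts and were not run. Median-ratio, upper-quartile and equal-sum scalings stood in for the normalizations. A depth of 21.4 to 35.4 M reads puts 1 read on a transcript of 1 kilobase at 0.0283 to 0.0468 FPKM, so values near 0.1 FPKM, such as Padi1 in Znf750_cKO, rest on few reads.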

Other observations

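All tests below other than the counts over splits of the libraries were chosen after the result was seen, as were the genes named in the first 2 paragraphs.

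Beside the immune list, 8 genes picked for their values, with no count of related genes that did not change, were also lower in Znf750_cKO. The complement chains C1qa, C1qb and C1qc fell from 22.0 ± 5.66 to 2.78 ± 0.56, from 27.8 ± 5.10 to 3.84 ± 0.41 and from 21.0 ± 6.00 to 2.89 ± 0.61 FPKM (n = 3 per group, limma adjusted p = 0.00089, 0.00027 and 0.0021). The class II gene H2-Aa fell from 7.04 ± 2.69 to 0.27 ± 0.21 FPKM (adjusted p = 0.0038), and H2-Eb1 and H2-Ab1 fell with log2 changes of -1.83 and -1.75 (adjusted p = 0.014 and 0.020, and 0.051 and 0.062 with the block). The chemokine receptor Cx3cr1 fell from 3.48 to 0.32 FPKM and the mannose receptor Mrc1 from 2.60 to 0.19 (adjusted p = 0.015 and 0.039, and 0.054 for Mrc1 with the block). H2-Aa, C1qa, C1qb and C1qc passed in each fit that leaves out 1 library, H2-Eb1 in 5 of 6, Cx3cr1 in 4, H2-Ab1 in 3 and Mrc1 in 1. Cd207, a marker of Langerhans cells, was at most 0.06 FPKM in any library, too low to compare the groups. Its level alone does not settle whether cells of that lineage were present at this age.

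Of 6 more genes picked in the same way, 3 fell and 3 rose. Krt79, a keratin of the follicle opening, fell from 348 ± 95.8 to 132 ± 13.9 FPKM (log2 change -1.35, limma adjusted p = 0.020), and the hair keratin-associated gene Krtap3-2 fell from 17.02 ± 6.85 to 5.28 ± 0.68 (adjusted p = 0.025). Skint10, of a family that shapes epidermal T cells, fell from 6.92 ± 1.73 to 1.23 ± 0.28 FPKM (adjusted p = 0.0047). The growth factor Epgn rose from 1.77 ± 0.08 to 7.47 ± 1.08 FPKM, the signalling scaffold Card14 from 3.99 ± 0.48 to 11.6 ± 2.44, and the calmodulin-like gene Calm5 from 48.1 ± 11.8 to 142 ± 11.1 (adjusted p = 0.0024, 0.0087 and 0.0062). Card14 lies within 5 Mb of Zfp750, where a chromosome segment that differs between the groups is not excluded (see the last paragraph). Krt79 passed in 1 of 6 fits that leave out 1 library and Krtap3-2 in 2, and Skint10, Epgn, Card14 and Calm5 in all 6.

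The 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 577 changed genes and the highest other split 5. It gave 11 lists past camera and the other splits 2 to 10, so the number of camera calls hardly marks the real split. In both cases 1 split, the real one, gave a result as large. If the numbers are taken as pairs, 3 other splits part all 3 pairs, with at most 1 gene and 10 lists, and 6 part 1 pair, with at most 5 genes and 7 lists.

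Immune markers were lower in Znf750_cKO, with a median log2 change of -2.33 (SD of members 0.39). Less dermis in the Znf750_cKO suspensions would lower fibroblast markers alike, but their median was -0.11 (SD 0.39), with -0.20 for Postn, -0.04 for Dcn and 0.06 for Sparc, against -1.07 for Vim, which immune cells also express (limma adjusted p = 0.052). These values argue against less dermis as the whole cause. Blood in the control suspensions stays open: erythroid markers had a median log2 change of -1.65 (SD 0.40, 3 members), less than the immune markers but within their joint spread, and summed globin was 34.0 ± 16.9 FPKM in control and 8.32 ± 2.11 in Znf750_cKO, from 0.18 to 0.29 of the summed immune markers in control and 0.38 to 0.47 in Znf750_cKO. A different recovery of immune cells from the suspension, or fewer such cells in the epidermis, may lie behind the change and was not tested.

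Krt2 and Krt8 had the highest log2 changes of the named genes, 7.62 and 5.75. If reads of Krt1 or Krt5 had been assigned to them at the same rate in both groups, their ratio to Krt1 and Krt5 would have stayed. The smallest log2 change of these ratios was 5.58. Assignment in the Znf750_cKO libraries alone, or from other paralogs, was not tested. Merkel cells, which express Krt8, would bring their other markers, but the summed rise of the other 6 Merkel markers was 0.87% of that of Krt8. A shared rise of simple-epithelial keratins was also not found, since Krt7, Krt18, Krt19 and Krt20 had a median log2 change of 0.31 and 1 of the 4 rose. A change of both genes within keratinocytes is a candidate explanation that these values leave open, found and tested on the same data.

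The third replicates of both groups stood apart on the first component. Genes of the X and Y chromosomes are not the whole cause, since the deviations of these libraries correlated at 0.47 across genes without them. A stronger immediate early response is a candidate explanation of part of it: 9 of 14 such genes were highest in replicate 3 of both groups, where chance gives 1.56. Sex, read here from Xist, and a shared day or litter, which the labels do not give, stay open, and genes are not independent replicates.

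Changed genes around Zfp750 were counted as a test of whether a chromosome segment beside the targeted locus differs between the groups. Within 10 Mb, 13 of 168 tested genes changed, or 7.74% against 4.16% elsewhere (two-sided Fisher exact p = 0.031, adjusted over 3 windows 0.093), with 6 of 106 within 5 Mb and 15 of 264 within 20 Mb. The smallest adjusted p was 0.093 and the odds ratio's interval within 10 Mb ran from 0.999 to 3.43, so such a segment may or may not be present. The bound that would have excluded it was set after the counts were seen. Changed genes within 5 Mb include Card14 (119307768 to 119345375), which rose. They also include Sectm1a (121067407 to 121081220), picked for its value, which fell from 4.42 ± 0.69 to 1.10 ± 0.03 FPKM (limma adjusted p = 0.0061). For both, an effect of Zfp750 loss and one of such a segment cannot be told apart here.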
